A study of Mus musculus with 4 samples.

How the data were processed

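Total RNA from 32D-EpoR cells with and without Epo was labelled with Cy3 from 200 ng of input, per the labels' protocols, by priming on the poly(A) tail, and hybridised to Agilent mouse arrays. There were 4 arrays, 2 per group, all on 1 slide with 1 scan, so slide and scan could not differ between the groups. The deposited files are the scanner output of Feature Extraction 10.1.1.1, per the file headers. Each holds a processed intensity for 62976 spots, which the authors' scanner software had corrected for background and for spatial trends, with surrogate values for the dimmest spots, per the file headers. It also holds the raw mean intensity of each spot and the median intensity of its local background, per the file headers. None of these values was scaled between arrays. The submitters' processing notes name limma, without a version or a role.

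From these, the log2 of the processed intensity was taken, and the 75th percentile over the 59305 non-control spots of each array was subtracted, with the mean of the 4 percentiles added back. The percentile lay at 224 and 250 intensity units without Epo and at 347 and 454 with Epo. Outlier spots were left out, which removed 9 probes, and no spot was marked as saturated. Spots of 1 probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 group, which left 23735 probes of 17569 genes. Each gene was represented by its kept probe with the highest mean. Among 1210 called genes with several kept probes, 116 had a probe that moved the other way. A gene that was not well above background on either array of a group has only a bound. It compares the mean of the brighter group with the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value well above background.

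Gene names in the files are those of the array design. They were updated through a RefSeq gene table of the assembly GRCm38.p6, used for names alone because the probe positions are on mm9. Of 55681 probes, 26413 were matched by accession, 3859 by symbol and 735 by synonym, and 24674 kept the name in the file.

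Epo was compared with no Epo with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The model had 2 residual and 4.57 total degrees of freedom. The median SE of a log2 change was 0.15, and the smallest change past the threshold was 0.43. The median SD between spots of 1 probe within an array ran from 0.0625 to 0.0982. Gene lists were written from textbook knowledge, and 34 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Lists overlap in part, and several genes stand in more than 1 list.

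The gene lists, the rule for named genes and all but 1 of the alternatives were fixed before the data were examined. The rule takes Fam210b, Epor and the heme enzymes whatever their values. It adds the 10 largest rises and 10 largest falls past the threshold that have a symbol, the same sign in both replicate numbers and more than a bound. From each list it takes up to 2 rises and 2 falls past the threshold, or the 2 members with the smallest p where none passes. It ends with the 3 largest bounds in each direction. Of the genes it gives, 3 are not reported here.

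The design text speaks of 2 independent experiments on cells of different passages. The replicate numbers were read as those experiments, which pairs the samples across groups. Same-numbered samples deviated from their group means with a correlation of 0.386 across genes, which are not independent replicates. The fit with the replicate number as a block had 1 residual degree of freedom. In it limma called 0 genes different by replicate number, with 4170 of 17569 at an unadjusted p under 0.05. With so few degrees of freedom the 0 calls do not exclude a difference between the experiments. The main fit leaves the pairing out, and its median SE was 0.145 against 0.0792 with the block.

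The steps were tested on simulated data with the means of the 17569 genes and 200 changed genes. Spreads were drawn from the distribution that limma fitted, with independent normal noise and no pairing of experiments. The fit recovered 0 of the 200 genes at a log2 change of 1, 84.5% at a log2 change of 2 and 98% at a log2 change of 4. A second simulation gave the 4804 called genes their estimated changes and all others 0. It recovered 71.2% of them, and 3.72% of its calls were false. Noise was drawn as the model assumes, so this share does not test the model. The adjusted threshold is stricter with 200 changed genes than with 4804. The first recovery rates thus do not give the power in the data, where changes down to 0.43 passed. The estimated changes of the second simulation are themselves picked by the test and so tend to be too large.

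Alternatives covered the background correction (normexp with an offset of 50 on the raw intensities), quantile normalization, no scaling, 2 other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust, the replicate block, other thresholds, and leaving out each array. Under 50% of probes were well above background, so the percentile over probes detected on all 4 arrays was added after seeing the data.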

Results

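Gene expression was measured in 32D-EpoR cells, an interleukin-3-dependent mouse myeloid progenitor line that carries an introduced erythropoietin receptor. Erythropoietin (Epo) is the hormone that drives red cell formation. Cells were taken out of the conditioned medium that sustains them and then either given Epo at 10 U/ml or left without it. How long Epo was present is not given in the sources used here. Each condition was measured on 2 single-colour arrays from 2 independent experiments, which limits the precision of every value below. Of 55681 gene probes, 41.5% and 41.3% were well above background on the arrays without Epo, and 42.7% and 47.9% on those with Epo. The arrays correlated at 0.993 within the group without Epo, at 0.995 within the group with Epo, and at 0.971 to 0.976 between the groups, across the genes tested, which are not independent replicates. The first principal component held 79.7% of the variance and parted the 2 groups, and the second held 14.3% and parted the replicate numbers.

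The comparison asked which transcripts respond to Epo, and the series title names Fam210b as a target. Fam210b, which encodes a mitochondrial protein, rose with Epo. Its log2 scaled signal was 6.72 ± 0.030 (SD, n = 2) without Epo and 8.38 ± 0.0018 (SD, n = 2) with Epo. The rise was 1.66 ± 0.11 (SE) on the log2 scale, or 3.16-fold, with a limma adjusted p of 0.0046, and it was present in both replicate numbers. The array carries 1 probe for the gene, under the older name 2010011I20Rik, with the sequence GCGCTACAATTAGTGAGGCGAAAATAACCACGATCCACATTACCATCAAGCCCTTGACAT. The file places it on chromosome 2 from 172178905 to 172178964 in the mouse build mm9. Whether that stretch is coding or untranslated was not analysed here. The call was lost when dim probes were not removed (adjusted p 0.109, within a range of 3.63e-12 to 0.109 over 13 alternatives).

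Epor, the receptor gene, fell by 1.60 ± 0.17 (SE) on the log2 scale (limma adjusted p 0.0082). Whether its probe also reads the introduced receptor is not known. Among the heme synthesis enzymes, Alas1, the housekeeping form of the first enzyme of the pathway, rose by 0.81 ± 0.12 (SE) with an adjusted p of 0.013. A second Alas1 probe gave 0.10, and the call was lost when the probes were averaged (adjusted p 0.113) and without replicate 1 or 2 of the Epo group (0.0542 and 0.0674). It held in 9 of 13 alternatives, over which the adjusted p ran from 1.46e-05 to 0.158. Fech, the ferrochelatase that puts iron into the ring, differed by -0.034 ± 0.16 (SE). The changes of Cpox and Uros were 0.29 and 0.017. Those of Ppox, Alad and Urod were -0.29, -0.15 and -0.14. Fech and these 5 enzymes did not pass the threshold. Without scaling Cpox and Uros did, with changes of 1.03 and 0.76 (limma adjusted p 0.00492 and 0.0385). The median change of all genes was itself 0.685 without scaling, so these passes do not show a rise relative to other genes. Alas2, the erythroid form of the first enzyme, was not well above background. The list of heme enzymes as a set was not called by camera (adjusted p 0.731), which put it higher although its median was -0.089. Adjusted over the list alone, 1 gene rose.

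**Figure D1:**
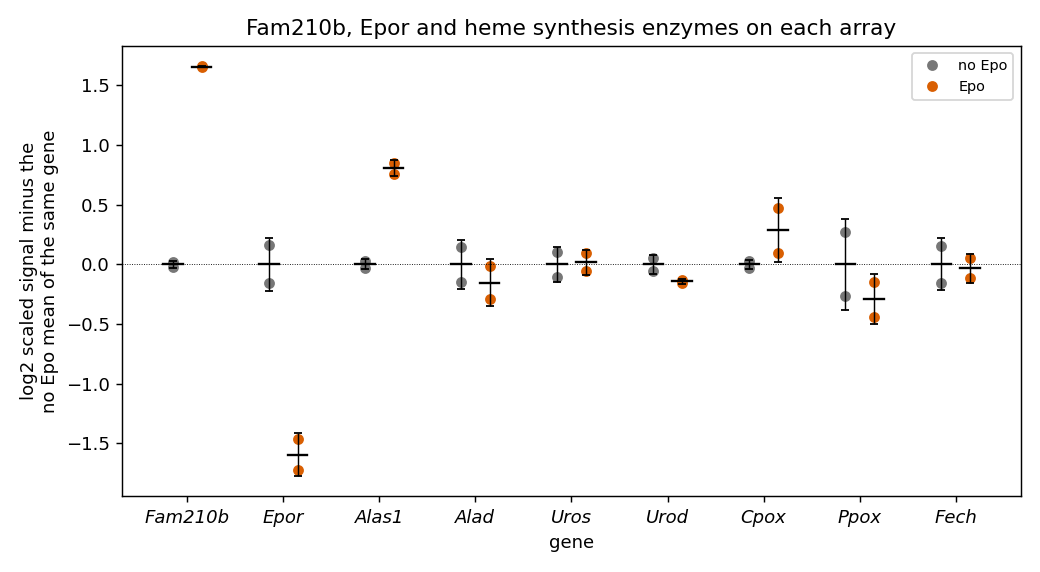
Log2 scaled signal of Fam210b, Epor and heme synthesis enzymes on each array, with the no Epo mean of the same gene subtracted; points are arrays, bars are group means and whiskers are 1 SD (n = 2). Fam210b lay 1.66 higher and Epor 1.60 lower with Epo, while the points of both groups overlapped for Alad, Uros, Ppox and Fech.

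Across the transcriptome, 17569 genes were tested. The ranks that follow hold among genes past the threshold with a symbol, more than a bound and the same sign in both replicate numbers. The feedback inhibitor Socs1 rose most, by 6.60 ± 0.28 (SE) on the log2 scale. It was followed by the immediate-early transcription factor Egr1 (5.53), the MYC family gene Mycn (5.09) and the interleukin-2 receptor chain Il2ra (5.03). Usp17le-ps, Slfn2, Egr2, Rasgrp3, Hbegf and Sema7a rose by 4.70, 4.60, 4.57, 4.50, 4.50 and 4.29. The first of these belongs to a family of nearly identical copies, so which copy its probe reads is uncertain. Among these genes with more than a bound, the germ-cell transcription factor Sohlh2 showed the largest fall, at -4.13 ± 0.23 (SE). Genes with only a bound are given below and can have fallen further. Among genes with more than a bound, Tlr12, the quiescence-linked cyclin Ccng2, the histone gene H3c1 and Klhl24 came next, at -3.24, -3.11, -3.08 and -2.93. Mc5r, Plxdc1, Ypel2, the transcriptional repressor Bcl6 and Adam12 followed at -2.79, -2.74, -2.68, -2.66 and -2.60. Egr1 and Egr2 were well above background on 1 of the arrays without Epo, and Plxdc1 on 1 of those with Epo, so their sizes and ranks rest in part on background. With 1 array left out Egr1 ran from 4.899 to 6.17, Egr2 from 3.997 to 5.145 and Plxdc1 from -3.14 to -2.33.

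In total 2302 genes rose and 2502 fell at a limma adjusted p of 0.05, which is 27.3% of those tested. Of these, 990 rose and 977 fell by at least 2-fold. With the replicate number as a block, 3499 rose and 4072 fell, and 4722 genes passed in both fits. All changes are relative to the 75th percentile of each array. The arrays with Epo were brighter, and the median change of all genes was -0.062 after scaling and 0.685 without scaling. The split of 2302 against 2502 was 1878 against 3651 when the percentile was taken over detected probes, and 8244 against 365 without scaling. Without scaling 16 named genes that fell lost their call while their direction held. Another 13 named genes turned from below to above 0. Among them were the called falls Hba-a2, Cebpa, Mki67, Pmvk, Ddit3, Slc16a3, Ern1, Hspa8 and Ppia. Among the 101 named genes besides Fam210b, 26 lost their call when at least 1 of the arrays was left out, and none of the 20 above was among them. Of the 101 genes, 93 were called with all 4 arrays and so had a call to lose. A further limit concerns the brightest genes. Of 333 genes with a mean level above 17, limma called 86 lower and 0 higher, and 0 were higher even at an unadjusted p under 0.05. Their median of -0.40 was 0.35 without scaling, and 4 of the 86 passed under quantile normalization, which sets equal ranks of all arrays to equal values.

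**Figure D2:**
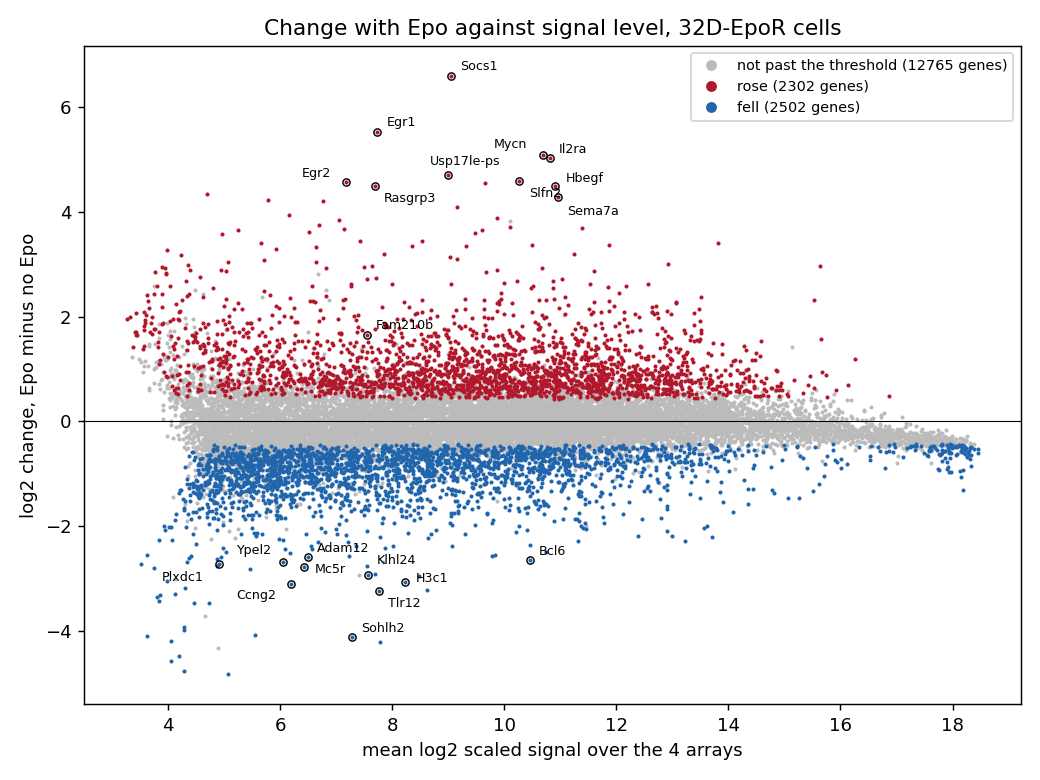
Log2 change with Epo against the mean log2 scaled signal of each of the 17569 genes tested, with genes that rose in red and genes that fell in blue. Circled are Fam210b and the 10 largest rises and 10 largest falls past the threshold among genes with a symbol and more than a bound. The 333 genes above a level of 17 have a median of -0.40, which was 0.35 without scaling.

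For some genes 1 group gave only a bound. With Epo the signal of an unnamed predicted transcript was at least 11.4-fold higher, that of 6430571L13Rik at least 9.62-fold higher and that of Usp17le at least 7.72-fold higher. Ly6k, the inhibitory receptor gene Pdcd1 and Igkv4-53 were at least 14.7-fold, 13.6-fold and 7.74-fold lower with Epo. In all, 210 genes that rose and 40 that fell had a bound in place of a level in 1 group.

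Known targets of the receptor's STAT5 pathway rose together. Of 23 tested, 18 rose and 1 fell over all genes tested, and 19 rose and 2 fell adjusted over the list alone. Socs1 and Il2ra led, and the kinase gene Pim1, the feedback inhibitor Cish and Myc rose by 3.70, 3.42 and 3.37. These last 3 genes were chosen after their values were seen. The median of the list was 1.95, or 1.55 with its gene that has only a bound at that bound. Gfi1b, a repressor needed for erythroid development, fell by 1.25. The list was called higher by camera (adjusted p 1.12e-09), with an adjusted p of 0.317 with an estimated correlation. No list passed with an estimated correlation, and that p is given beside each list called with the preset one. That test refers each list to 2 residual degrees of freedom, which raises every p, so hardly any list could pass. The STAT5 list went from an unadjusted camera p of 6.58e-11 to 0.0187, although its estimated correlation was below the preset one. The estimate itself rested on the same 2 degrees of freedom. It lay below the preset one for the STAT5, ribosome biogenesis, mitochondrial biogenesis, cholesterol, FOXO, histone and lymphoid lists (-0.165 to -0.0235). For the other lists called it lay above (0.0141 to 0.231). Lists of both kinds lost their call, so the loss does not show that gene correlation removes the calls. Among immediate-early and feedback genes of the ERK pathway, 10 of 18 rose, led by Egr1 and Egr2, and 2 fell (12 and 3 adjusted over the list alone). Jun and the phosphatase gene Dusp1 were the falls, at -2.36 and -1.57. Camera called the list higher (adjusted p 0.000822, and adjusted p 0.442 with an estimated correlation).

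Genes of ribosome biogenesis, which build the translation machinery, rose in most cases. Of 37 tested, 29 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 1.19 on the log2 scale. Polr1b, a subunit of RNA polymerase I, rose by 2.44, and Rrp9, a nucleolar protein of rRNA processing, by 2.29. Camera gave an adjusted p of 7.03e-13, and the adjusted p 0.317 with an estimated correlation. Of 25 genes of mitochondrial biogenesis and import, 10 rose and 0 fell (12 and 0 adjusted over the list alone). The import chaperones Timm10 and Timm9 rose by 2.21 and 2.04. For this list the camera adjusted p was 5.09e-05, and the adjusted p 0.319 with an estimated correlation. Among 32 respiratory chain and ATP synthase subunits, by contrast, limma called 0, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. Camera did not call this list (adjusted p 0.977). Ndufs1 and Cycs had the smallest p among them, with changes of 0.33 and 0.30.

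Of 21 genes of the unfolded protein response, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The transcription factor Xbp1 and the co-chaperone Dnajb9 rose by 1.57 and 1.20, and the stress sensor Ern1 fell by 0.54, although it lay at 0.21 without scaling. The camera adjusted p was 0.000133, and the adjusted p 0.343 with an estimated correlation. Of 24 cholesterol genes, 6 rose and 2 fell (9 and 2 adjusted over the list alone, 12 and 2 with the replicate block). Msmo1 lay at 1.095, and Acat2 and Pmvk at -1.15 and -0.44. Pmvk lay at 0.30 without scaling. The camera adjusted p was 0.0398, the call was lost under quantile normalization (0.106) and held in 9 of 14 alternatives that use camera (1.05e-05 to 0.430), the highest of them with an estimated correlation. In the list of ATF4 and amino acid genes 6 of 26 rose and 1 fell (6 and 1 adjusted over the list alone). The amino acid carrier Slc7a1 and Atf4 itself rose by 1.74 and 0.94, and Ddit3 fell by 0.51, although it lay at 0.23 without scaling. Its camera adjusted p was also 0.0398, and the call was lost under quantile normalization (0.162). It held in 7 of 14 alternatives that use camera (0.000268 to 0.442), the highest of them with an estimated correlation.

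Genes of the G1/S transition and DNA replication were lower with Epo relative to other genes. Of 37 tested, 0 rose and 20 fell (1 and 22 adjusted over the list alone), with a median of -0.55, which was 0.20 without scaling. E2f2, a transcription factor of the cell cycle, fell by 1.99, and the thymidine kinase gene Tk1 fell by 1.28. Camera gave an adjusted p of 9.40e-06, and the adjusted p 0.319 with an estimated correlation. Of 10 histone genes 8 fell (9 adjusted over the list alone), with a median of -1.10, or -0.36 without scaling. H3c1 and H3c14 were lowest, at -3.08 and -2.19, and near-identical copies make the single histone gene uncertain. For the histone list the camera adjusted p was 0.000133, and the adjusted p 0.319 with an estimated correlation. Of 34 genes of G2 and mitosis 4 fell (0 adjusted over the list alone, 11 with the replicate block). The falls included Ccnf at -0.81 and Mki67 at -0.64, the latter at 0.11 without scaling. The median of the 34 genes, -0.23, was 0.52 without scaling. The list had a camera adjusted p of 0.0398, which was 0.308 with the normexp background and 0.468 with an estimated correlation. It was called in 5 of 14 alternatives that use camera (0.00407 to 0.758).

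Inhibitors of the cell cycle were lower as well. Of 10 tested, 6 fell (1 rose and 6 fell adjusted over the list alone), with Ccng2 at -3.11 and Cdkn2c at -1.69. This list had a camera adjusted p of 0.0380, which was 0.0688 with the replicate block and 0.442 with an estimated correlation. It was called in 8 of 14 alternatives that use camera (0.00439 to 0.442). FOXO targets and other genes tied to cytokine withdrawal fell in 12 of 22 cases (14 adjusted over the list alone), with Ccng2 and Bcl6 lowest. For these genes the camera adjusted p was 0.00104, and the adjusted p 0.319 with an estimated correlation. The medians of both lists, each -0.77, were -0.020 and -0.019 without scaling. Of 9 pro-apoptotic BCL2 family genes 4 fell (4 adjusted over the list alone), led by Bmf and Bcl2l11 at -1.95 and -1.50, but the list was not called (camera adjusted p 0.129). It was called lower under quantile normalization (0.0437), within a range of 0.0437 to 0.442 over 14 alternatives that use camera. Among 10 anti-apoptotic genes 3 rose and 1 fell (4 and 2 adjusted over the list alone). The survival gene Bcl2l1 rose by 1.54 and Bcl2a1d, one of several near-identical copies, by 0.91, whereas Birc2 fell by 0.83. Without scaling Birc2 lay at -0.083, and its call held in 9 of 13 alternatives (adjusted p 0.0061 to 0.831). The list was not called (camera adjusted p 0.292).

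The tested genes of the erythroid lineage did not rise as a set. Of the genes on the array, 14 of 18 erythroid regulators, 3 of 8 globin genes and 15 of 30 red cell membrane and enzyme genes were tested. Of 14 erythroid regulators 1 rose and 6 fell (2 and 6 adjusted over the list alone). Mafk rose by 0.70, and Epor and Lmo2 fell by 1.60 and 1.29. The call of Mafk held in 8 of 13 alternatives (adjusted p 5.98e-05 to 0.179). It was lost with the percentile over detected probes (0.0519), without a filter on dim probes (0.179), without replicate 1 or 2 of the Epo group (0.0639 and 0.145) and without replicate 2 of the group without Epo (0.1003). The list was not called (camera adjusted p 0.212). Of 3 globin genes Hba-a2 fell by 0.61 with an adjusted p of 0.0490 (1 of 3 adjusted over the list alone), and its near-identical copy leaves the gene uncertain. Without scaling it lay at 0.14, its adjusted p was 0.0561 with the replicate block, and it passed in 5 of 13 alternatives (0.0291 to 0.712). Of 15 red cell membrane and enzyme genes Xk rose by 1.02 and none of the other 14 passed (also 1 adjusted over the list alone). With the normexp background the change of Xk was 0.22 with an adjusted p of 0.169, the highest of 13 alternatives from 6.37e-07 up, of which 10 kept the call. It was also lost without replicate 2 of the Epo group (0.0584). Among 21 iron genes 3 rose (1 adjusted over the list alone), including the transferrin receptor Tfrc at 1.53 and the iron sensor Fbxl5 at 0.89. The call of Fbxl5 held in 9 of 13 alternatives (adjusted p 4.11e-06 to 0.179). Of 13 genes of heme and porphyrin transport 2 rose (1 adjusted over the list alone), the heme-degrading Hmox1 at 0.99 and the heme exporter Flvcr1 at 0.92. Camera called none of these 4 lists (adjusted p 0.497, 0.622, 0.292 and 0.502).

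Markers of other blood lineages moved in part. Of the markers on the array, 7 of 14 lymphoid, 4 of 12 macrophage and 3 of 12 stromal genes were tested. Of 7 lymphoid genes 5 fell (7 adjusted over the list alone), with Cd3e and Cd4 at -1.14 and -0.81, and the list was called lower (camera adjusted p 0.00532, and adjusted p 0.346 with an estimated correlation). Its median of -0.75 was -0.0035 without scaling. Of 23 granulocyte and monocyte genes 3 fell (1 adjusted over the list alone). With the replicate block 1 rose and 8 fell. The 3 falls included Csf1r at -0.79 and Cebpa at -0.74, which lay at -0.042 and 0.0097 without scaling. This list had a camera adjusted p of 0.139, and of 0.0469 with the replicate block, within a range of 0.0469 to 0.818 over 14 alternatives that use camera. Of 12 mast cell and basophil genes Mitf rose by 1.14, and Gzmb and Hdc fell by 1.18 and 0.88. Of 11 megakaryocyte genes 3 fell, with Selp, which was well above background on 1 of the arrays with Epo, at -1.10 and Itgb3 at -0.96. Of 4 macrophage genes Apoe and Adgre1 rose by 1.18 and 1.03. Of 11 stem and progenitor genes Etv6 rose by 0.56 and Lmo2 fell by 1.29. Of 3 stromal genes Pecam1 rose by 0.75. Adjusted over the list alone these counts were the same, except for 1 more fall among the macrophage genes and 1 more rise among the megakaryocyte genes. Camera called none of these last 5 lists (adjusted p 0.151, 0.278, 0.246, 0.497 and 0.328).

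Of 20 interferon-stimulated genes 3 rose and 8 fell (3 and 9 adjusted over the list alone). Ifit1 and Rsad2 fell by 2.60 and 2.44, and Irf9 rose by 0.98. Ifit1 was well above background on 1 of the arrays with Epo. The list was not called (camera adjusted p 0.0981). It was called lower relative to other genes under quantile normalization (0.0482) and without scaling (0.0131), although its median was 0.44 without scaling. Over 14 alternatives that use camera its adjusted p ran from 0.0131 to 0.758. Of 14 cytokines and chemokines 6 rose and 3 fell, with Osm and Il6 at 4.09 and 2.59 and Cxcl10 and Csf1 at -2.15 and -1.27 (camera adjusted p 0.0599). Of 19 genes in the list of JAK-STAT components 5 rose and 2 fell. The rises include the transferrin receptor gene Tfrc at 1.53, an iron gene and not a JAK-STAT component. It stands in the counts and the set test of this list. Il4ra rose by 3.34, although its other probe gave 0.23, and Il6ra fell by 1.42 (camera adjusted p 0.729). Of 22 glycolysis genes 3 rose and 2 fell, with Hk2 and Slc2a3 at 2.33 and 1.07 and Pfkfb4 and Slc16a3 at -1.08 and -0.70, the last at 0.048 without scaling (camera adjusted p 0.729). Of 9 heat shock genes 4 rose and 1 fell, among them Hsph1 and Chordc1 at 1.05 and 0.71. Hspa8 was called lower at -0.49, but its other probes reached 0.75 and it lay at -0.19 under quantile normalization and 0.26 without scaling (camera adjusted p of the list 0.345). Of 14 reference genes Ppia was called lower at -0.57. It lies among the brightest genes, and under quantile normalization its change was -0.087 with an adjusted p of 0.659, the highest of 13 alternatives from 0.00524 up, and without scaling 0.18 (camera adjusted p of the list 0.197). Adjusted over the list alone, the counts of these last 5 lists were the same, except for 2 more falls among the JAK-STAT components and 0 calls among the reference genes.

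**Figure D3:**
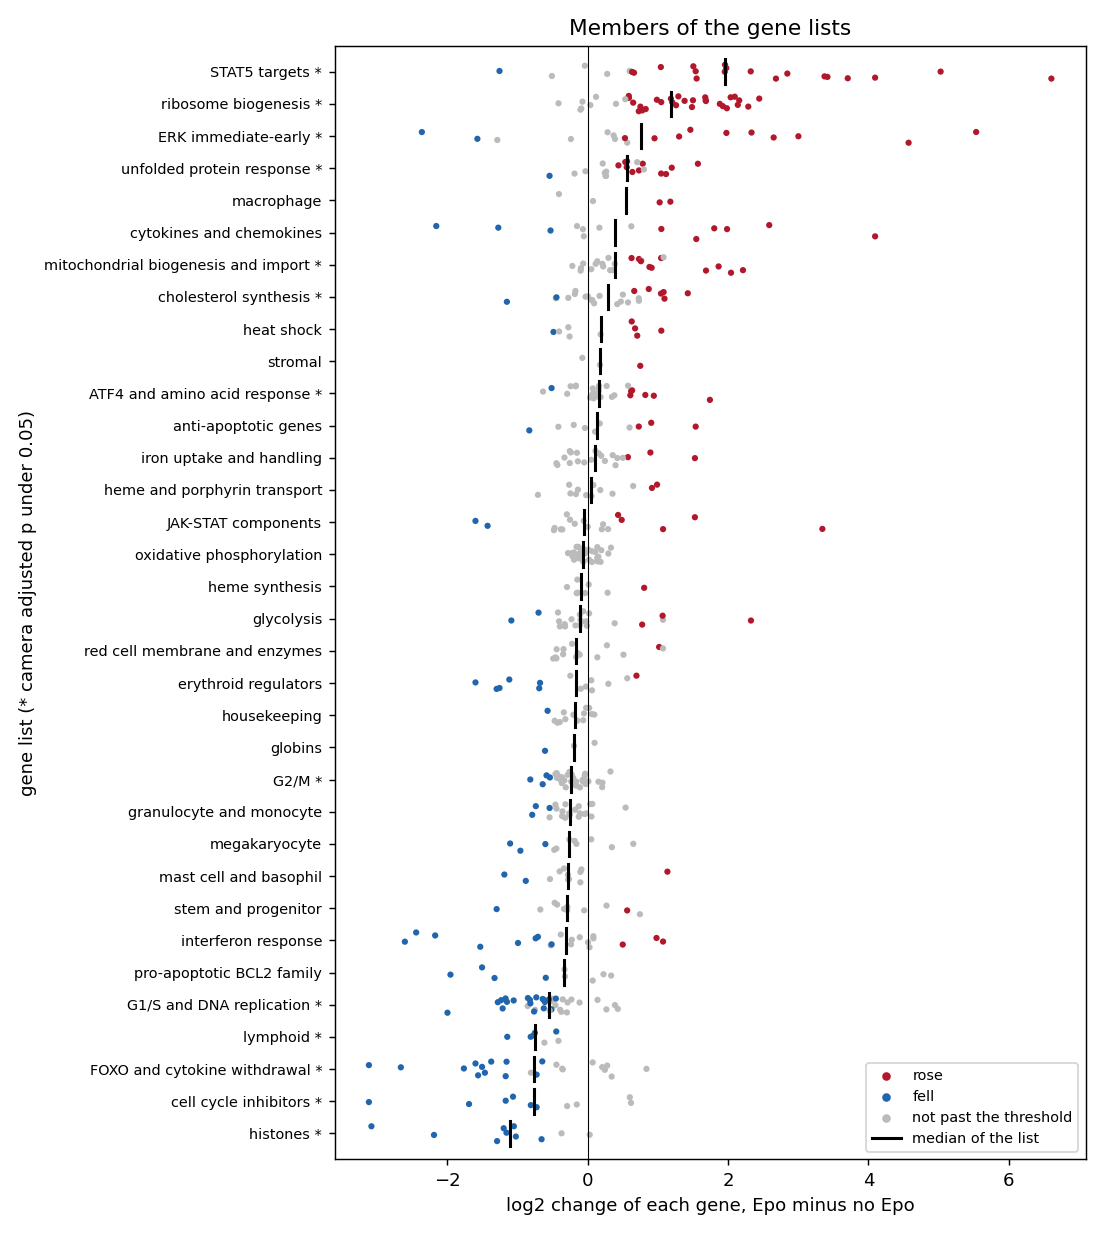
Log2 change with Epo of every tested member of the 34 gene lists, with members that rose in red, members that fell in blue and list medians as black bars. Medians run from -1.10 for the histone genes to 1.95 for the STAT5 targets. Without scaling the only medians below 0 were those of the histone, FOXO, cell cycle inhibitor and lymphoid lists. They lay at -0.36, -0.019, -0.020 and -0.0035. The median difference of the spike-in controls was -0.317, so relative to them all medians would lie higher, and scaling to them was not run.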

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

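The percentile over detected probes was chosen after seeing the data. Fam210b rose under all 13 alternatives, by 1.13 (normexp) to 2.40 (no scaling) (log2), and passed the threshold in 12. Without a filter on dim probes its rise was 1.66 with an adjusted p of 0.109. In that setting limma called 0 genes higher and 0 lower, although 7157 had an unadjusted p under 0.05, since it tested 36408 genes with a median SE of 0.292 against 0.145. It called 11 lists higher. The number of genes that rose and fell was 8244 and 365 without scaling, 3499 and 4072 with the replicate block, and 990 and 977 at 2-fold or more, and 3802 fell at an adjusted p of 0.10. Without scaling the prior gave every gene nearly 1 pooled spread (35140 total degrees of freedom). Leaving out 1 array at a time left 1102 to 2019 genes that rose and 1178 to 1945 that fell, with the lowest counts without Epo replicate 1. A lone array was then assumed to vary like the other group. Named genes that lost their call numbered 24 and 20 without Epo replicates 1 and 2, and 7 and 15 without no Epo replicates 1 and 2. Ddit3, Ern1, Etv6, Hba-a2, Hspa8, Pmvk and Ppia lost it in all 4 runs. Cebpa, Chordc1, Fbxl5, Mafk, Mki67, Pecam1 and Slc16a3 lost it in 3, Alas1, Birc2, Ccnf, Csf1r and Flvcr1 in 2, and Atf4, Bcl2a1d, Cd4, Hdc, Hmox1, Slc2a3 and Xk in 1. Lists that lost theirs numbered 1, 2, 4 and 1. Cytokines and chemokines gained a call without Epo replicate 1 (adjusted p 0.0229) and without no Epo replicate 1 (0.0343), and also without a filter (0.00112), without scaling (0.00162) and with the percentile over detected probes (0.0339), within a range of 0.00112 to 0.591 over 14 alternatives that use camera. Interferon genes gained one under quantile normalization (0.0482) and without scaling (0.0131), and pro-apoptotic genes under quantile normalization (0.0437). Without a filter, anti-apoptotic, iron and heme transport genes gained one (0.0139, 0.00692 and 0.0389). Cpox, Uros, Ndufs1 and Cycs passed without scaling (0.00492, 0.0385, 0.00319 and 0.00449), Ndufs1 and Cycs with normexp (0.0313 and 0.0152), Ndufs1 with trend and robust (0.0479) and Cycs with the mean of its probes (0.0455). Calls were lost with normexp for Hba-a2, Xk, Pmvk, Ddit3 and Hspa8, with the mean of probes for Alas1, Mki67 and Pmvk, with quantile normalization for Hspa8 and Ppia, and with the percentile over detected probes for Mafk. Without scaling 16 falls lost theirs, with changes from -0.68 for Il6ra to -0.042 for Csf1r. The others were Gfi1b, Lmo2, Tk1, Ccnf, Birc2, Cd4, Cd3e, Hdc, Gzmb, Itgb3, Selp, Acat2, Pfkfb4 and Csf1. With 1 array left out Fam210b stayed between 1.64 and 1.68, the lists called higher numbered 5 to 8 and those called lower 4 to 6. With an estimated correlation camera called 0 lists higher and 0 lower (against 13 with the preset correlation), and fry, which does not compare a list with other genes, called 11 higher and 13 lower. The replicate block ended the calls of Hba-a2 and the cell cycle inhibitors, added the granulocyte and monocyte list, and changed no other call of a named gene or list. A slide block was not run, since there is 1 slide.

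Directions turned for genes and lists with changes near 0 or below the shift of 0.746 that scaling removes. Without scaling, the log2 changes were 0.59 for Alad, 0.60 for Urod, 0.45 for Ppox, 0.71 for Fech, 0.14 for Hba-a2, 0.0097 for Cebpa, 0.11 for Mki67, 0.30 for Pmvk, 0.23 for Ddit3, 0.048 for Slc16a3, 0.21 for Ern1, 0.26 for Hspa8 and 0.18 for Ppia. Fech was at 0.085 with normexp. Uros was at -0.077 with quantile normalization and at -0.11 with the percentile over detected probes, and Hspa8 at 0.22 with the mean of its probes. With 1 array left out Uros ran from -0.088 to 0.12 and Fech from -0.19 to 0.12. For lists the direction is that of the set test and the value the median minus that of all genes. Glycolysis was at 0.088 with normexp, 0.084 with quantile normalization, -0.043 without scaling and 0.34 without a filter. Heme synthesis was at -0.14 with quantile normalization and -0.027 with the block, heme and porphyrin transport at -0.027 and JAK-STAT components at -0.080 with quantile normalization, and red cell genes at -0.10 without scaling. Without a filter the granulocyte list was at 0.19 and the stem cell list at 0.062. Oxidative phosphorylation was at -0.0022 with the mean of probes and at 0.00072 with the block, fry and the percentile over detected probes. With 1 array left out, glycolysis ran from -0.085 to -0.0029, heme synthesis from -0.13 to 0.082 and oxidative phosphorylation from -0.039 to 0.088. Apart from the shift that scaling removes, causes of these differences were not tested. Of all comparisons with an alternative, 1086 for genes and 430 for lists kept direction and side of the threshold, 187 and 36 fell below it, 8 and 23 rose above it, and 21 and 20 turned.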

Other observations

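The tests in this part were chosen after the results they bear on were seen, apart from the camera test and the comparison of the brightest genes with quantile normalization, and the family members named were chosen by their values. Genes were also grouped by the stem of their symbol, which gave 352 families of at least 5 among 11370 tested genes, of which 14.8% rose and 13.04% fell. Rises were over-represented, by a one-sided hypergeometric test adjusted over both directions, in 7 families. The Socs feedback inhibitors rose in 6 of 7 cases (adjusted p 0.0224), with Socs3 and Socs6 at 2.68 and 2.03. The tRNA methyltransferase family Trmt rose in 9 of 16 cases (adjusted p 0.0241), led by Trmt61a at 3.20. Genes with the stem Eif, which are translation initiation factors but also kinases, binding proteins and pseudogenes, rose in 19 of 58 cases, with an adjusted p of 0.0453 close to the threshold and Eif1a and Eif2b3 at 2.07 and 1.66. Helicases of the Ddx family rose in 14 of 34 (adjusted p 0.0241) and the nucleolar families Utp and Nop in 7 of 10 and 6 of 8 (adjusted p 0.0241 and 0.0261), although 5 of the 8 Nop genes also stand in the ribosome biogenesis list. Genes with the stem Usp, most of them deubiquitinases, rose in 19 of 46 cases (adjusted p 0.00817). They include 5 near-identical Usp17 copies, of which 4 rose, and without these copies 15 of 41 rose (unadjusted p 0.000471). Under quantile normalization the medians of these 7 families stayed above 0, from 0.28 for Eif to 1.47 for Socs. The other scalings shift all genes by 1 amount and leave a family's place among them unchanged. Without scaling the median of all genes was itself 0.685, so medians above 0 there decide nothing.

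The next 3 families by adjusted p were the DNA helicase subunits Mcm, of which 6 of 10 fell (adjusted p 0.0564), the Gimap GTPases, of which 5 of 7 rose (adjusted p 0.0892), and the clamp loader subunits Rfc, of which 4 of 5 fell (adjusted p 0.091). Their medians were -0.52, 1.39 and -0.81, and without scaling 0.22, 2.13 and -0.061. Gimap5 rose by 3.38 and is the largest change of its family. Genes share regulation, so that these p-values overstate the evidence from 4 arrays. Counts of calls per list were also set against 10000 random lists of the same signal levels, adjusted over 68 counts. Of the lists called by camera, those of G2 and mitosis, cholesterol, and ATF4 and amino acid genes did not pass. In the first 4 of 34 fell, against a median of 3 in the random lists. In the other lists the rises, 6 of 24 and 6 of 26, had adjusted p 0.483 and 0.436 in this test. Of the lists not called by camera, 5 passed. Falls were more frequent among erythroid regulators (6 of 14, adjusted p 0.0105), interferon-stimulated genes (8 of 20, adjusted p 0.0256) and pro-apoptotic genes (4 of 9, adjusted p 0.0325), and rises among heat shock genes (4 of 9, adjusted p 0.0176) and cytokines and chemokines (6 of 14, adjusted p 0.0499). Whether these counts hold under the other scalings was not tested.

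The brightest genes were lower with Epo, with a median of -0.40 that was 0.35 without scaling. Above a mean level of 17, a bound picked from the plot of change against level, limma called 86 of 333 genes lower and 0 higher, with 0 higher at an unadjusted p under 0.05. Of these 86 genes, 4.65% were past the threshold under quantile normalization. That value decides nothing, because the method gives equal ranks equal values and so takes the brightest genes to about 0 whatever lowered them. Without scaling, the brightest spike-in control differed by 0.024 between the groups and the next brightest by -0.196, against a median of -0.318 for all but the brightest. The brightest thus differed less than the others, by 0.294 on the log2 scale. This is consistent with a compression of signals at the bright end, so these falls, which make up 3.44% of all falls, may be technical. It rests on a single spike-in, and a true fall of these genes was not excluded.

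Arrays with Epo were brighter, by 0.75 on the log2 scale at the 75th percentile. With equal amounts of spike-in in each sample, brighter labelling, hybridisation or scanning would raise the spike-in controls alike, but their median difference was -0.317. Spike-in amounts were not analysed here, so this holds only if they were equal. Dim probes do not account for the brighter arrays, since over probes well above background on all arrays the rise was 0.871. The gap between gene probes and spike-ins was 1.06. With equal spike-in amounts it could come from more sample RNA in the labelling or a larger share of mRNA in total RNA with Epo. These 2 readings cannot be told apart, because RNA amounts were not analysed here.

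DNA replication and histone genes were lower relative to other genes, with medians of -0.55 and -1.10 that were 0.20 and -0.36 without scaling, while ribosome biogenesis genes, Myc and Mycn were higher. A trend with signal level would place such lists among random lists of the same levels, but their medians lay at percentiles 0, 0 and 100 of 10000. Neither was it due to 1 experiment alone, since in each replicate number the 3 medians lay at least 0.438 from that of all genes on the same side. No biological explanation was tested. Labelling starts at the poly(A) tail, which most replication-dependent histone transcripts lack, and what share of them was read was not analysed here.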
